A study of Mus musculus with 6 samples.

How the data were processed

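The series measured RNA from mouse prostate luminal cells, the secretory epithelial cells that line the prostate's glands, by RNA sequencing. Per the labels' protocols, a transgene placed mouse Csf1 under the rat probasin promoter, which is active in prostate luminal cells. Luminal cells of C57BL/6 transgenic mice aged 4 months and of wild-type (WT) littermates were isolated by fluorescence-activated cell sorting, and the sort markers are not given in the sources used here. Transgenic libraries are called CSF1 here, after the genotype field. Each group had 3 libraries, and both groups carry the numbers 3, 5 and 8 in their titles. The labels do not state what these numbers mean or whether each library came from a separate animal, so the p-values measure only the spread between these samples.

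Per the labels' protocols, cDNA was made with the SMART-Seq v4 kit from both random and oligo-dT primers, and libraries were sequenced on an Illumina HiSeq instrument. The labels name both the Nextera XT and the TruSeq DNA kit for library construction, and the step that was used is not settled by them. Neither kit marks the strand of origin, so reads of overlapping genes on opposite strands are not separated by strand. Per the submitters' processing notes, reads were processed with bcl2fastq 1.8.3, TopHat and Cufflinks against mm10, and the TopHat and Cufflinks versions are not stated.

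The authors deposited 1 Cufflinks isoform table per library, with 34535 RefSeq transcripts of 24346 gene symbols, whose values are FPKM (fragments scaled to transcript length and to each library's mapped fragments) per the file headers. The bounds of Cufflinks' confidence interval are also FPKM in the deposited tables. The deposited coverage column holds a signal, the mean read depth over a transcript, and was checked to be 1 constant times FPKM within each table. This constant rises with sequencing depth. It was 3.19, 3.50 and 2.72 in WT replicates 3, 5 and 8 and 4.17, 5.01 and 4.37 in the CSF1 replicates, so the CSF1 libraries were the deeper ones. The tables give no fragment totals, so the number of fragments behind each value is not given. A status column marks loci that Cufflinks skipped for too many fragments (HIDATA, written as 0) or failed to estimate (FAIL).

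From these tables, FPKM of transcripts sharing a gene symbol were summed. The 9 genes with a HIDATA or FAIL status in any library were left out, a choice made after the data had been examined. They included Amd1, Amd2, Chd9, Sbp, Sbpl, Spink1, Tpm3 and Zfp281. The 10951 genes with a mean of at least 1 FPKM over the 6 libraries were tested. A gene near 0 in 1 group passed this filter only where it was high in the other, so lists of genes low in WT lean to rises. FPKM was used as deposited with no further scaling, as log2(FPKM + 1), in R 4.3.3 with limma 3.58.1 and the package data.table at version 1.17.8. The test was limma's moderated statistic with an intensity trend (not robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes in log2 units are on the log2(FPKM + 1) scale, which understates changes of genes with low values. Csf1, Csf1r and Il34 were also tested by an exact two-sided permutation test of the difference in mean log2(FPKM + 1). With 3 libraries against 3, the smallest p this test can give is 0.1.

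Gene lists were written before the data were examined, as were the tests, the naming rule and the alternatives not described as added later. There were 34 lists with 661 genes, of which 658 were in the tables. They covered luminal identity, androgen-regulated secretory products, luminal progenitor markers, basal, macrophage, lymphocyte, neutrophil, stroma, endothelial, neuroendocrine, seminal vesicle and red blood cell markers, interferon-stimulated genes, NF-kB inflammation, gp130 and STAT3 signalling, chemokines, MHC class I and class II presentation, senescence-associated secretion, epithelial-mesenchymal transition, EGFR ligands and feedback, Wnt and Notch targets, immediate early genes, S phase, G2 and mitosis, p53 targets, prostate cancer drivers, glycolysis and hypoxia, oxidative phosphorylation, NRF2 targets, the unfolded protein response, cholesterol synthesis, lipogenesis and ribosomal proteins. The 31 lists with at least 5 tested members were tested with limma's camera, two-sided, with the correlation between genes preset to 0.01 and adjustment over these 31 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. None of the camera calls held with an estimated correlation. For the remaining 3 lists (neutrophil, seminal vesicle and neuroendocrine) values are given without a test.

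The genes named were chosen by a rule. It took Csf1, its receptor gene Csf1r and the receptor's other ligand gene Il34. It took the 12 largest rises and the 12 largest falls among genes past the threshold that changed at least 2-fold in mean FPKM + 1 with no overlap between the groups' libraries, leaving out symbols of predicted and small RNA genes. From each list it took up to 4 members with the smallest limma p and the members past the threshold. Genes named outside the rule are said to be chosen after their values were seen.

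Whether the title numbers pair libraries was checked from each library's deviations from its group's mean over the tested genes. Libraries with the same number in the 2 groups had correlations of 0.257 (number 3), 0.111 (number 5) and 0.182 (number 8) across genes, each above 0.1, so the numbers were treated as pairing the samples in the alternative with a replicate block. Genes are not independent replicates, and the labels give no source for the pairing.

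The alternatives were pseudocounts of 0.1 and 5, quantile normalization, median-ratio scaling, a replicate block, no expression filter, a mean of at least 5 FPKM, robust limma, array weights, each transcript on its own, other thresholds, and leaving out each library and each same-numbered pair. Keeping the genes with a failed status, and leaving out genes whose exons overlap another listed gene, were added after the data had been examined. A rescaling of FPKM to the genes outside the 5 most abundant was added later, after all results had been seen. It divides each library by the share of FPKM outside its 5 most abundant genes, multiplies by the mean of that share and does not centre the genes. That share was 75.7%, 82.1% and 80.1% in WT replicates 3, 5 and 8 and 83.4%, 87.7% and 91.04% in the CSF1 replicates. The same rescaling was also run on shares among the genes with no failed status, since Cufflinks skipped some dominant genes in the WT libraries. Exon positions came from GENCODE M21 (GRCm38), and an overlap of at least 1 bp of exons counted. All 10 splits of the 6 libraries into 3 and 3 were fitted in the same way.

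The fit was tested on simulated data for 10950 genes with 200 genes changed between CSF1 and WT, 40 at each size. At a log2 change of 1, 60% of the changed genes were recovered, at 2 95%, at 3 100%, at -1 47.5% and at -2 97.5%. Of 169 genes called, 9 (5.33%) had not been changed. A raised list was recovered and 0 of 20 unchanged lists were called. The simulated noise was drawn separately for each gene, so list members were not correlated. The simulation therefore does not check camera's preset correlation. The changed genes all had a WT mean log2(FPKM + 1) of at least 3, so the recovery does not cover lower genes. The simulation held no shift common to all genes and far fewer changed genes than the 3549 called in the real data. Its 5.33% therefore does not measure false calls among those.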

Results

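RNA of sorted prostate luminal cells was profiled in 3 WT and 3 CSF1 libraries, each library giving FPKM for 34535 transcripts. Between 9926 and 10089 genes lay above 1 FPKM in the WT libraries and between 11102 and 11231 in the CSF1 libraries. The coverage per FPKM, which grows with depth, was 2.72 to 3.50 in WT and 4.17 to 5.01 in CSF1. The 5 most abundant genes held 24.3%, 17.9% and 19.9% of all FPKM in WT replicates 3, 5 and 8. In CSF1 replicates 3, 5 and 8 they held 16.6%, 12.3% and 8.96%. These shares do not cover the same genes in both groups, because Spink1, Sbp and Sbpl were skipped and written as 0 in every WT library, while at least 1 of them was among the 5 in each CSF1 library. Among genes with no failed status, the 5 most abundant held 24.5%, 17.99% and 19.96% in WT and 12.7%, 11.5% and 7.13% in CSF1. Values below are mean ± SD over the 3 libraries of a group, WT before CSF1, unless stated otherwise. Changes are log2 changes of CSF1 over WT.

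The comparison asks how forced expression of colony-stimulating factor 1, a growth factor of the macrophage lineage, changes gene expression in the luminal cells of the prostate. The Csf1 gene itself came first, as a check of the labels. Its 3 listed transcripts span 107741048 to 107760469 on the minus strand of chromosome 3 (GRCm38). Csf1 was at 1.54, 2.25 and 3.98 FPKM in WT replicates 3, 5 and 8 and at 1082, 1326 and 1678 FPKM in the CSF1 replicates. Its mean rose 526-fold, from 2.59 ± 1.25 to 1362 ± 299.97 FPKM, with a log2 change of 8.60 ± 0.26 (SE; limma adjusted p = 7.84e-07; exact permutation p = 0.1, n = 3 per group). Csf1r, the gene of the CSF1 receptor (chromosome 18, 61105572 to 61131139), is expressed by macrophages and rose from 0.499 ± 0.276 to 24.0 ± 14.2 FPKM (log2 change 3.93 ± 0.36, limma adjusted p = 0.000113, exact permutation p = 0.1). Il34 encodes the receptor's other ligand (chromosome 8, 110741829 to 110805924) and rose from 0.341 ± 0.373 to 6.67 ± 1.73 FPKM (log2 change 2.52 ± 0.27, limma adjusted p = 0.000238, exact permutation p = 0.1).

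**Figure D1:**
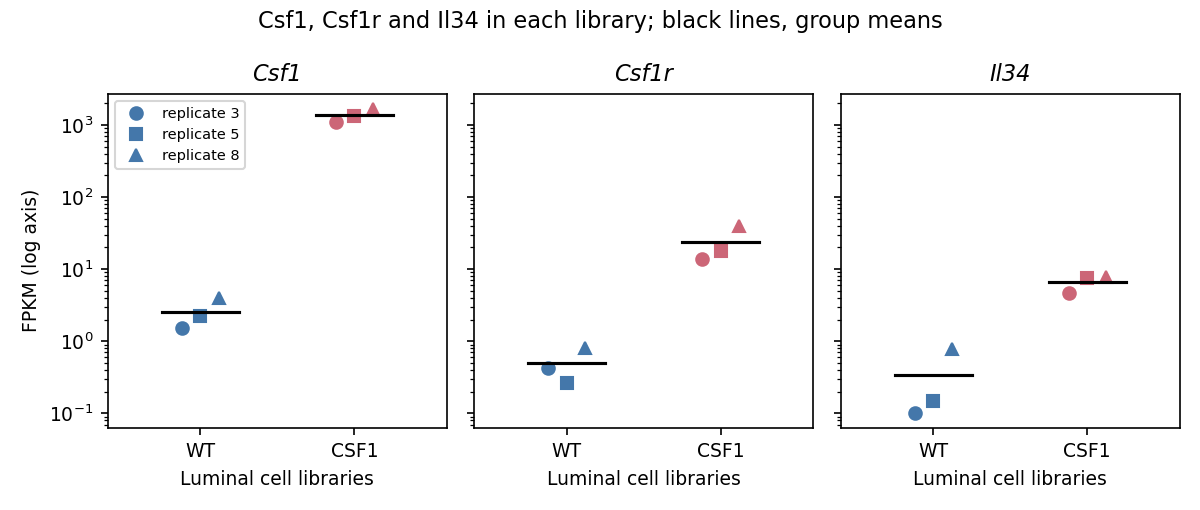
FPKM (log axis) of Csf1, Csf1r and Il34 in each WT and CSF1 library, with black lines at the group means and a symbol per replicate number. All CSF1 libraries lie above all WT libraries for each gene, with Csf1 at 1082 to 1678 FPKM in CSF1 and at 1.54 to 3.98 FPKM in WT.

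**Figure D2:**
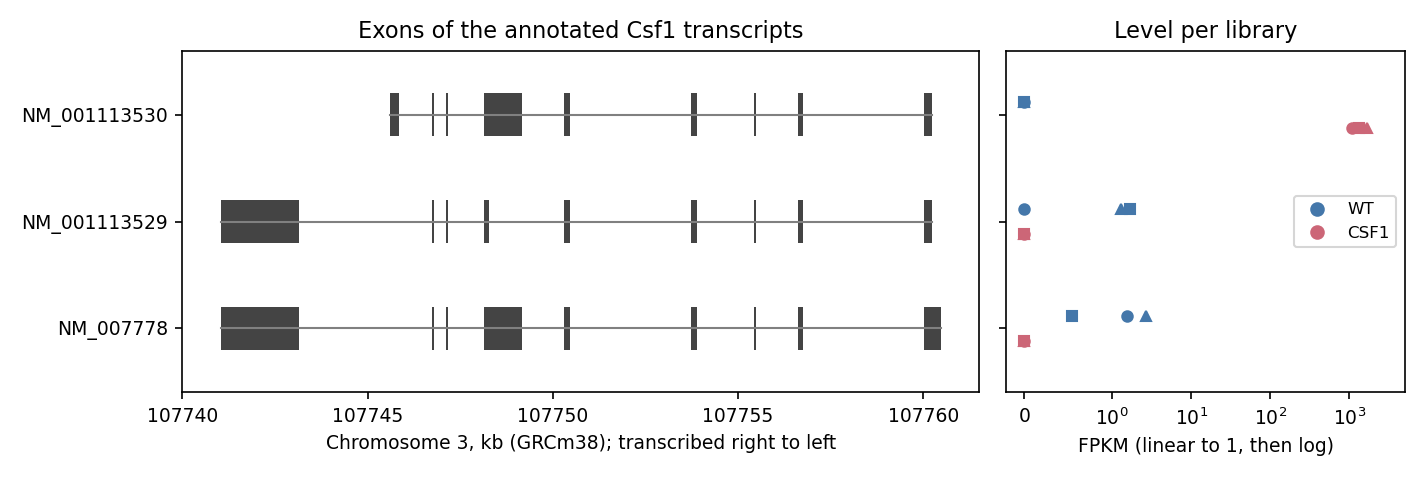
Exons of the 3 annotated Csf1 transcripts on chromosome 3 (GRCm38, kb, transcribed right to left) and the FPKM of each transcript in each library (linear to 1, then log), with WT in blue and CSF1 in red. NM_001113530 lies at 1082 to 1678 FPKM in the CSF1 libraries and at 0 in the WT libraries.

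CSF1 luminal libraries had higher levels of inflammatory, interferon-stimulated and antigen-presentation genes. They also had higher levels of markers of progenitor-like luminal cells and of basal cells, macrophages and stroma. Genes of protein folding in the endoplasmic reticulum, of cholesterol synthesis and of prostate secretion were lower as lists. General luminal markers did not pass camera as a list. These calls rest on camera's preset correlation, and none of the list calls held with an estimated correlation. By limma, 3549 of 10951 tested genes passed an adjusted p of 0.05, with 2731 higher and 818 lower in CSF1, and 4667 genes had an unadjusted p under 0.05. Among those that passed, 1630 rose and 270 fell at least 2-fold, and 98 rose and 7 fell at least 16-fold. In 5229 genes (47.7%) the groups did not overlap, where chance gives 10%, and 3537 of these passed the threshold. The median log2 change of all tested genes was 0.17. The balance of directions depended on the scaling, since 77.0% of called genes were higher with FPKM as deposited, 41.8% with quantile normalization, 56.0% with median-ratio scaling and 64.3% with FPKM rescaled to the genes outside the 5 most abundant (60.9% with failed-status genes left out of that rescaling). The median of all genes moved to -0.16, -0.01 and 0.05 (0.02) under these scalings. Changes of gene lists are therefore also given relative to all genes, and no list that passed changed the sign of its median under quantile normalization or median-ratio scaling. Among lists that did not pass, the median fell below 0 for p53 targets (-0.11) and NRF2 targets (-0.01) with quantile normalization, and for oxidative phosphorylation with quantile normalization and median-ratio scaling (-0.16 and -0.17). The number of lower genes was 478 without WT replicate 5 and 526 without WT replicate 8. It was 485 without both libraries numbered 8. Without both libraries numbered 5, 1519 genes were higher and 341 lower.

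Csf1 had the largest rise by the naming rule, and 11 other genes followed. Wfdc18, which encodes a secreted WAP-domain protein, rose from 1.58 ± 1.17 to 733 ± 116 FPKM, a log2 change of 8.26. Ccl20, a chemokine gene of inflamed epithelium, rose from 0.666 ± 0.623 to 562 ± 386 FPKM (log2 change 8.25). Lcn2, which encodes an iron-scavenging protein, rose from 17.2 ± 9.35 to 2535 ± 1317 FPKM (log2 change 7.09). The serum amyloid gene Saa3 was at 0, 1.26 and 0.348 FPKM in WT replicates 3, 5 and 8 and at 267, 127 and 413 FPKM in CSF1, and Saa1 rose from 3.52 ± 2.73 to 283 ± 216 FPKM. The lactoferrin gene Ltf, also a neutrophil granule gene, was at 0.0124, 0 and 0.640 FPKM in WT and at 147, 60.7 and 119 FPKM in CSF1. Pglyrp1, which encodes a peptidoglycan recognition protein, rose from 3.42 ± 1.28 to 310.03 ± 68.3 FPKM. The interferon-induced gene Ifi27l2a was listed at 0 in all 3 WT libraries and was at 106, 79.0 and 164 FPKM in CSF1. Genes of the Ly6 surface antigens rose, Ly6c1 from 7.94 ± 1.81 to 840.3 ± 128 FPKM and Ly6a, which encodes the stem cell antigen Sca-1, from 29.6 ± 13.1 to 1808 ± 314 FPKM. H2-Ab1, an MHC class II gene, rose from 10.02 ± 5.81 to 655 ± 481 FPKM. Over these 12 genes, log2 changes ran from 5.80 to 8.60 and limma adjusted p-values from 7.16e-07 (Ly6c1) to 0.000206 (Saa1).

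Among the 12 largest falls were 6 secretoglobin genes of 1 family, which encode small secreted proteins. Scgb2b15 was the most abundant and fell from 1119 ± 497 to 97.4 ± 25.3 FPKM (log2 change -3.43, limma adjusted p = 0.000173), and Scgb2b7 fell from 105 ± 40.7 to 6.69 ± 4.84 FPKM (log2 change -3.89). Scgb2b27 fell from 76.0 ± 49.2 to 0.741 ± 0.722 FPKM and Scgb2b20 from 45.2 ± 9.04 to 1.11 ± 0.7497 FPKM. Scgb1b29 fell from 10.4 ± 2.26 to 0.133 ± 0.231 FPKM and Scgb1b20 from 33.0 ± 5.04 to 0.102 ± 0.0974 FPKM. Sequence similarity within the family was not measured, and reads shared between members would make the values of single members uncertain. Kcnk3, a potassium channel gene, fell from 159 ± 49.6 to 5.55 ± 0.590 FPKM (log2 change -4.56 ± 0.23, limma adjusted p = 6.66e-06), and its exons overlap another listed gene. Crabp1, which encodes a retinoic acid binding protein, fell from 142 ± 37.8 to 12.5 ± 4.78 FPKM (log2 change -3.43 ± 0.30, limma adjusted p = 9.71e-05). Lrrc52 fell from 40.01 ± 14.1 to 3.01 ± 1.56 FPKM. The last 3 of the 12 were listed at 0 in every CSF1 library. Hcfc1r1 was at 44.6, 49.4 and 63.0 FPKM in WT replicates 3, 5 and 8, Emc9 at 15.3, 16.5 and 19.0 FPKM and Lppos at 10.9, 12.8 and 17.4 FPKM. The exons of all 3 overlap those of another listed gene on the opposite strand.

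Transcripts of inflammatory response genes were higher in CSF1. Of 23 NF-kB and inflammatory response genes tested, 22 rose, 0 fell and 1 did not pass (22 rose when adjusted over the list alone), with a median log2 change 2.87 above that of all genes (camera adjusted p = 4.08e-11, and adjusted p = 0.271 with an estimated correlation). Among them, Il1b rose from 5.64 ± 4.70 to 293 ± 202 FPKM, Il6 from 7.99 ± 2.06 to 126 ± 47.0 FPKM, Tnf from 1.67 ± 0.899 to 37.2 ± 18.8 FPKM and the feedback inhibitor Nfkbia from 86.0 ± 15.3 to 370.3 ± 68.1 FPKM. The gp130 and STAT3 list, which holds the receptors, kinases and targets of the interleukin 6 family, had 27 tested members, of which 23 rose, 0 fell and 4 did not pass (23 rose when adjusted over the list alone). Its median was 1.90 above all genes (camera adjusted p = 3.83e-09, and adjusted p = 0.271 with an estimated correlation). Socs3 rose from 6.29 ± 1.02 to 74.0 ± 21.1 FPKM, Osmr from 1.43 ± 0.516 to 23.1 ± 5.96 FPKM and Lrg1 from 26.8 ± 3.54 to 539 ± 113 FPKM, and Stat3 itself from 35.2 ± 3.14 to 70.8 ± 7.83 FPKM. Among 23 chemokine genes, 19 rose, 0 fell and 4 did not pass (22 rose when adjusted over the list alone), and the median was 2.92 above all genes (camera adjusted p = 5.61e-08, and adjusted p = 0.271 with an estimated correlation). Cxcl1 rose from 28.9 ± 12.3 to 393 ± 202 FPKM, Ccl2 from 40.7 ± 31.4 to 714 ± 363 FPKM and Cxcl17 from 64.3 ± 24.9 to 418 ± 8.80 FPKM. Macrophages also express several of these genes, and 5 of the chemokine genes are members of another list.

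Of 30 interferon-stimulated genes, 29 rose, 0 fell and 1 did not pass (29 rose when adjusted over the list alone), with a median 2.03 above all genes (camera adjusted p = 6.89e-12, and adjusted p = 0.271 with an estimated correlation). Irf7 rose from 6.77 ± 0.646 to 81.9 ± 28.1 FPKM, Isg15 from 8.26 ± 3.15 to 112 ± 59.0 FPKM and Oasl2 from 2.40 ± 0.877 to 42.2 ± 10.7 FPKM. MHC class I presentation moved with them. All 16 tested genes rose and 16 rose when adjusted over the list alone, with a median 1.36 above all genes (camera adjusted p = 2.47e-08, and adjusted p = 0.271 with an estimated correlation). H2-K1 rose from 408 ± 66.3 to 1414 ± 178 FPKM, B2m from 2326 ± 492 to 5079 ± 516 FPKM and the immunoproteasome gene Psmb8 from 21.01 ± 2.64 to 101 ± 21.4 FPKM. MHC class II genes, which professional antigen-presenting cells such as macrophages express, all rose (8 of 8, and 8 when adjusted over the list alone), with a median 5.13 above all genes (camera adjusted p = 1.64e-05, and adjusted p = 0.278 with an estimated correlation). Cd74 rose from 34.8 ± 17.1 to 1681 ± 1219 FPKM.

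Markers of other cell types were measured in the same libraries, since a sort can hold other cells. Of the lists tested for this, 5 rose (macrophage, stroma, basal, endothelial and lymphocyte). All 22 tested macrophage and monocyte markers rose, and 22 when adjusted over the list alone, with a median 3.71 above all genes (camera adjusted p = 9.72e-10, and adjusted p = 0.271 with an estimated correlation). Lyz2 rose from 26.1 ± 30.8 to 703 ± 579.9 FPKM, C1qa from 2.08 ± 1.58 to 94.0 ± 74.5 FPKM, Aif1 from 0.0618 ± 0.0650 to 32.2 ± 19.9 FPKM and Adgre1, which encodes F4/80, from 0.271 ± 0.114 to 9.05 ± 5.77 FPKM. The list's mean log2(FPKM + 1) rose from 1.25 ± 0.48 to 4.68 ± 0.86. All 15 fibroblast and smooth muscle markers rose, and 15 when adjusted over the list alone, with a median 3.29 above all genes (camera adjusted p = 6.46e-09, and adjusted p = 0.271 with an estimated correlation). Dcn rose from 95.2 ± 6.77 to 457 ± 64.1 FPKM, Col1a1 from 0.310 ± 0.228 to 15.1 ± 9.51 FPKM and Acta2 from 4.37 ± 1.46 to 28.9 ± 5.03 FPKM. Dcn and Col1a1 did not keep a constant ratio between the groups, and the source of Dcn in WT was not tested. The epithelial-mesenchymal transition list, whose genes fibroblasts also express, had 9 tested members and all rose, 9 when adjusted over the list alone, with a median 3.398 above all genes (camera adjusted p = 1.64e-05, and adjusted p = 0.271 with an estimated correlation). Vim, which is also a stroma marker, rose from 3.03 ± 0.964 to 47.7 ± 7.08 FPKM, and Fn1 from 0.252 ± 0.217 to 5.75 ± 0.443 FPKM. All 5 tested endothelial markers rose, also 5 when adjusted over the list alone, with a median 1.32 above all genes (camera adjusted p = 0.0141, and adjusted p = 0.271 with an estimated correlation). Plvap rose from 0.988 ± 0.441 to 6.32 ± 1.51 FPKM. Of 7 lymphocyte markers, 6 rose, 0 fell and 1 did not pass (7 rose when adjusted over the list alone), with a median 1.52 above all genes (camera adjusted p = 0.0183, and adjusted p = 0.459 with an estimated correlation). Their levels stayed low, and Cd3g rose from 0.207 ± 0.195 to 3.71 ± 2.52 FPKM. The lymphocyte list did not pass with a pseudocount of 5 (camera adjusted p = 0.0526, over a range of 0.00155 to 0.0526). Too few members were tested for the endothelial list without CSF1 replicate 5 and for the lymphocyte list without CSF1 replicate 8. Tested members were 9 of 18 listed for epithelial-mesenchymal transition, 5 of 13 for endothelial and 7 of 18 for lymphocyte markers. Members near 0 in WT entered only where they were high in CSF1, so the shares that rose and the medians lean upward. Over all listed members, mean log2(FPKM + 1) rose from 0.60 to 2.47, from 0.33 to 1.32 and from 0.18 to 1.18. These list calls held with no expression filter.

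Red blood cell genes did not pass. Of 5, 0 rose, 0 fell and 5 did not pass (0 rose when adjusted over the list alone), with a median 1.96 above all genes (camera adjusted p = 0.361, and adjusted p = 0.634 with an estimated correlation). The median log2 change of this list moved from 2.13 to 1.12 without CSF1 replicate 8. Hba-a1, which passed with the replicate block (limma adjusted p = 0.0196) and with array weights (0.0381), differed widely between libraries, at 294, 63.3 and 333 FPKM in WT replicates 3, 5 and 8 and at 402, 419 and 3765 FPKM in CSF1. Among neutrophil markers, S100a8 was listed at 0 in each WT library and was at 0.539, 1.68 and 26.8 FPKM in CSF1 replicates 3, 5 and 8 (limma adjusted p = 0.0872). S100a8 passed without CSF1 replicate 3 (limma adjusted p = 0.0259) and with a pseudocount of 0.1 (0.0156), and its adjusted p otherwise ran up to 0.220. S100a9 was at 0.859, 0.846 and 4.14 FPKM in CSF1, Ngp was listed at 0 in all 6 libraries, and Ltf rose as given above. Of the seminal vesicle markers, Ceacam10 was at 1.63, 2.63 and 1.996 FPKM in WT and at 19.2, 5.77 and 7.51 FPKM in CSF1 (limma adjusted p = 0.00739), and the highest of the other members in any library was Svs5 at 2.11 FPKM. Of the neuroendocrine markers, Calca alone was tested and did not pass (limma adjusted p = 0.839).

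**Figure D3:**
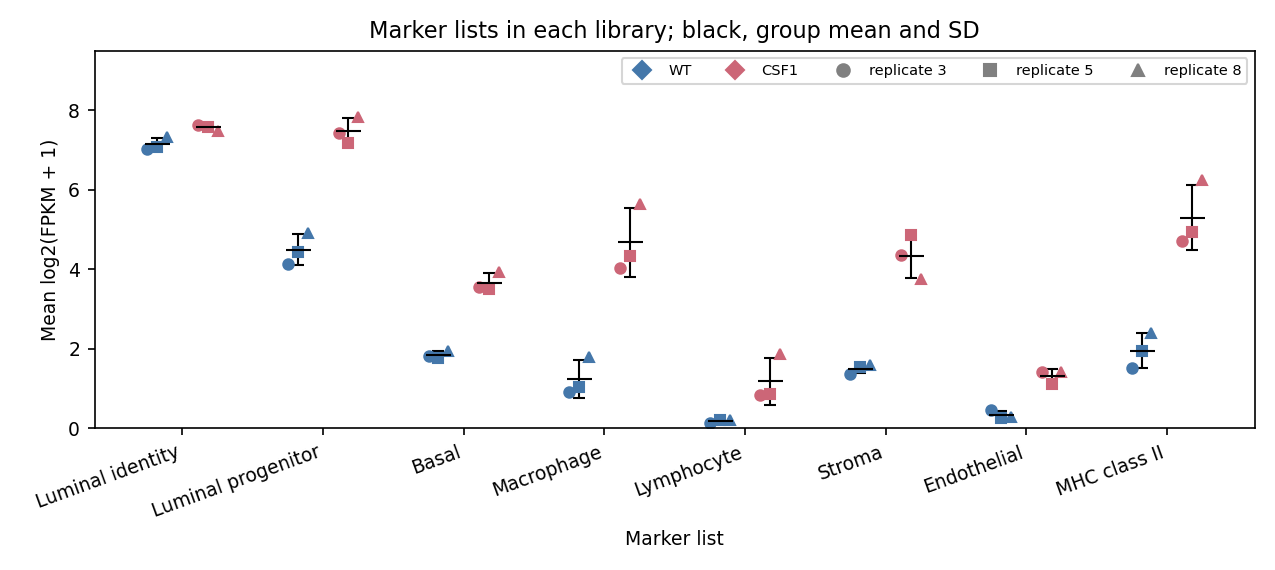
Mean log2(FPKM + 1) over the members of 8 marker lists in each library, with black bars for the group mean and SD and a symbol per replicate number. The macrophage list rose from 1.25 ± 0.48 to 4.68 ± 0.86 and the luminal progenitor list from 4.49 ± 0.39 to 7.48 ± 0.33, while luminal identity lay at 7.15 ± 0.15 to 7.57 ± 0.07.

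Among epithelial cell markers, those of proximal or progenitor-like luminal cells rose strongly. Of 16 tested, 14 rose, 0 fell and 2 did not pass (15 rose when adjusted over the list alone), with a median 3.22 above all genes (camera adjusted p = 1.24e-08, and adjusted p = 0.271 with an estimated correlation). Clu rose from 256 ± 47.5 to 4843 ± 891 FPKM, Wfdc2 from 41.1 ± 19.2 to 1374 ± 316 FPKM, Psca from 18.0 ± 5.83 to 98.7 ± 41.1 FPKM, Krt4 from 5.84 ± 0.299 to 42.7 ± 5.95 FPKM and Aldh1a3 from 0.469 ± 0.373 to 41.7 ± 10.7 FPKM. Basal markers rose as well. Of 12, 11 rose, 0 fell and 1 did not pass (11 rose when adjusted over the list alone), with a median 1.799 above all genes (camera adjusted p = 1.04e-06, and adjusted p = 0.271 with an estimated correlation). Krt5 rose from 2.65 ± 0.685 to 21.2 ± 7.46 FPKM, Krt14 from 8.98 ± 0.873 to 100.002 ± 36.3 FPKM and Krt15 from 23.3 ± 6.34 to 329 ± 25.8 FPKM. Luminal identity markers did not pass as a list. Of 16, 6 rose, 2 fell and 8 did not pass (6 rose and 2 fell when adjusted over the list alone), with a median 0.15 above all genes (camera adjusted p = 0.442, and adjusted p = 0.661 with an estimated correlation, and fry adjusted p = 0.00883). Elf3 rose from 60.9 ± 6.93 to 220.4 ± 32.2 FPKM, Prom1 from 5.24 ± 2.20 to 51.2 ± 14.9 FPKM and Cdh1 from 90.7 ± 16.4 to 189 ± 3.41 FPKM. In the other direction, Spdef and Hoxb13 fell, with log2 changes of -1.12 and -0.84. Over the alternatives their limma adjusted p ran up to 0.0876 and 0.114. Krt8 and Krt18, chosen after their values were seen, did not pass with FPKM as deposited. Krt8 passed as higher with the replicate block alone (limma adjusted p = 0.0452, 0.0452 to 0.714 over all alternatives). Krt18 passed as lower with quantile normalization alone (limma adjusted p = 0.0461, 0.0461 to 0.981 over all alternatives). Krt8 was at 1335 ± 347 to 1724 ± 528 FPKM and Krt18 at 2279 ± 337 to 2132 ± 476 FPKM.

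Androgen-regulated and secretory genes of luminal cells were lower as a list. Of 22, 2 rose, 5 fell and 15 did not pass (2 rose and 5 fell when adjusted over the list alone), with a median -0.68 relative to all genes (camera adjusted p = 0.000350, and adjusted p = 0.362 with an estimated correlation). The list did not pass with quantile normalization (camera adjusted p = 0.0639) or by fry (adjusted p = 0.109), and over the other alternatives its camera adjusted p went down to 1.92e-05. Its median log2 change of -0.51 depended on the libraries, at -0.31 without WT replicate 3, -0.18 without CSF1 replicate 8, -0.14 without both libraries numbered 8 and -0.97 without both numbered 5. Its mean log2(FPKM + 1) was 6.29, 5.896 and 6.05 in WT replicates 3, 5 and 8 and 5.81, 5.76 and 4.87 in CSF1. Trpv6 fell from 68.2 ± 24.0 to 6.21 ± 2.82 FPKM, Azgp1 from 1009 ± 204 to 236 ± 59.9 FPKM and Ggt1 from 65.0 ± 9.26 to 26.8 ± 5.96 FPKM. In the other direction, Pigr, which encodes the receptor that carries antibodies across epithelia, rose from 355 ± 128 to 968 ± 227 FPKM, and Tmprss2 rose from 33.4 ± 6.23 to 79.4 ± 11.6 FPKM. The abundant secretory genes Pbsn and Msmb, chosen after their values were seen, did not pass. Pbsn, whose rat counterpart supplied the transgene's promoter, was at 25228, 5909 and 8668 FPKM in WT replicates 3, 5 and 8 and at 11931, 8570.4 and 1615 FPKM in CSF1. Msmb was at 15696, 6722 and 9012 FPKM in WT and at 9145, 6934 and 1591 FPKM in CSF1.

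Genes of the unfolded protein response, which serve protein folding in the endoplasmic reticulum, were lower as a list. Of 22, 0 rose, 14 fell and 8 did not pass (15 fell when adjusted over the list alone), with a median -1.08 relative to all genes (camera adjusted p = 1.73e-10, and adjusted p = 0.271 with an estimated correlation). Hspa5, which encodes the chaperone BiP, fell from 3407 ± 467 to 1590.3 ± 323 FPKM, Herpud1 from 1226 ± 144 to 469 ± 114 FPKM, Creld2 from 527 ± 20.96 to 163 ± 53.4 FPKM and Ddit3 from 236 ± 45.5 to 85.7 ± 34.0 FPKM. Cholesterol synthesis genes were lower as a list, though most of them did not pass singly. Of 22, 0 rose, 10 fell and 12 did not pass (10 fell when adjusted over the list alone), with a median -0.69 relative to all genes (camera adjusted p = 3.07e-06, and adjusted p = 0.152 with an estimated correlation). Cyp51 fell from 19.0 ± 3.43 to 10.1 ± 0.390 FPKM and Idi1 from 27.4 ± 9.40 to 13.1 ± 1.51 FPKM. Ribosomal protein genes shifted by little. Of 34, 0 rose, 3 fell and 31 did not pass (1 fell when adjusted over the list alone), with a median -0.39 relative to all genes (camera adjusted p = 8.77e-07, and adjusted p = 0.362 with an estimated correlation). Oxidative phosphorylation genes did not pass. Of 31, 0 rose, 1 fell and 30 did not pass (0 rose when adjusted over the list alone), and the median log2 change of 0.04 was positive while camera's direction was down, since it lay -0.13 relative to all genes (camera adjusted p = 0.108, and adjusted p = 0.692 with an estimated correlation). The sign of that median depended on 1 library, since it was -0.03 without WT replicate 3. It was 0.06 without CSF1 replicate 3, 0.11 without WT replicate 8 and 0.01 without CSF1 replicate 8. This list passed as lower with median-ratio scaling (camera adjusted p = 0.00240), with FPKM rescaled to the genes outside the 5 most abundant (0.00929, and 0.00514 with failed-status genes left out) and without WT replicate 3 (0.0189), over a range of 0.00240 to 0.331. Lipogenesis genes did not pass. Of 14, 6 rose, 0 fell and 8 did not pass (6 rose when adjusted over the list alone), with a median 0.21 above all genes (camera adjusted p = 0.4001, and adjusted p = 0.634 with an estimated correlation, and fry adjusted p = 0.00881). Elovl5 rose from 12.1 ± 2.03 to 29.4 ± 1.07 FPKM. Of 20 NRF2 and oxidative stress genes, 5 rose, 4 fell and 11 did not pass (5 rose and 4 fell when adjusted over the list alone), with a median 0.07 above all genes (camera adjusted p = 0.863, and adjusted p = 0.935 with an estimated correlation, and fry adjusted p = 0.0467), and Gpx2 rose from 7.07 ± 2.66 to 252 ± 55.1 FPKM. Prdx6, Gstm1, Sod1 and Gstm2 fell, with log2 changes of -0.81, -0.65, -0.62 and -0.45.

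Growth and stress programmes rose in part. Of 16 EGFR ligand, receptor and feedback genes, 13 rose, 0 fell and 3 did not pass (13 rose when adjusted over the list alone), with a median 1.26 above all genes (camera adjusted p = 2.85e-05, and adjusted p = 0.152 with an estimated correlation). Dusp6 rose from 5.55 ± 0.886 to 74.0 ± 10.1 FPKM, Egfr from 4.60 ± 1.25 to 16.3 ± 2.22 FPKM and Tgfa from 1.51 ± 0.529 to 9.42 ± 2.71 FPKM. Of 18 S phase genes, 11 rose, 1 fell and 6 did not pass (11 rose and 1 fell when adjusted over the list alone), with a median 0.65 above all genes (camera adjusted p = 0.0157, and adjusted p = 0.271 with an estimated correlation), and Mcm6 rose from 4.04 ± 0.941 to 14.7 ± 0.491 FPKM. This list did not pass among genes with a mean of at least 5 FPKM (camera adjusted p = 0.301, over a range of 0.00366 to 0.301). Of 7 G2 and mitosis genes, 5 rose, 0 fell and 2 did not pass (5 rose when adjusted over the list alone), with a median 0.97 above all genes (camera adjusted p = 0.0357, and adjusted p = 0.362 with an estimated correlation), and Birc5 rose from 1.08 ± 0.721 to 5.48 ± 1.25 FPKM. The G2 and mitosis call was lost without WT replicate 3 (0.0524), CSF1 replicate 3 (0.116), CSF1 replicate 5 (0.09001), CSF1 replicate 8 (0.0597) or both libraries numbered 3 (0.0611), and with the replicate block (0.0555). It was also lost with a pseudocount of 0.1 (0.0527) and without genes of overlapping exons (0.203), and over the other alternatives its camera adjusted p went down to 0.00125. Only 7 of the 22 listed G2 and mitosis genes passed the expression filter, which favours rises among genes near 0 in WT. Macrophages and stroma can divide too, so the S phase and the G2 and mitosis genes are not specific to luminal cells. Of 13 Wnt and Notch targets, 8 rose, 0 fell and 5 did not pass (8 rose when adjusted over the list alone), with a median 0.55 above all genes (camera adjusted p = 0.0560, and adjusted p = 0.271 with an estimated correlation, and fry adjusted p = 0.00128), and Ccnd1 rose from 4.91 ± 0.480 to 16.7 ± 1.89 FPKM. The Wnt and Notch list passed without WT replicate 3 (0.0327) and without CSF1 replicate 8 (0.0471), with median-ratio scaling (0.0242), with FPKM rescaled to the genes outside the 5 most abundant (0.0337, and 0.0297 with failed-status genes left out), with no filter (0.00742) and with array weights (0.0357), over a range of 0.00742 to 0.117.

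Of 21 genes of senescence-associated secretion, 16 rose, 0 fell and 5 did not pass (18 rose when adjusted over the list alone), with a median 2.25 above all genes (camera adjusted p = 8.77e-07, and adjusted p = 0.271 with an estimated correlation). Igfbp7 rose from 10.8 ± 3.48 to 189 ± 94.5 FPKM and Plaur from 54.0 ± 21.4 to 286 ± 73.9 FPKM. Of 22 immediate early and dissociation stress genes, 11 rose, 1 fell and 10 did not pass (14 rose and 1 fell when adjusted over the list alone), with a median 0.49 above all genes (camera adjusted p = 0.00783, and adjusted p = 0.438 with an estimated correlation), and Fos rose from 638 ± 117 to 1203 ± 106 FPKM and Hspa1a from 500.4 ± 147 to 1318 ± 126 FPKM. Of 23 glycolysis and hypoxia genes, 10 rose, 1 fell and 12 did not pass (11 rose and 1 fell when adjusted over the list alone), with a median 0.31 above all genes (camera adjusted p = 0.0124, and adjusted p = 0.455 with an estimated correlation), and Slc2a1 rose from 77.5 ± 20.3 to 162 ± 20.8 FPKM. The median log2 change of this list moved from 0.48 to 0.29 without WT replicate 3 (camera adjusted p = 0.0333). The glycolysis and hypoxia call was lost without genes of overlapping exons (camera adjusted p = 0.0749, over a range of 0.000655 to 0.0749). Of 21 p53 targets, 7 rose, 0 fell and 14 did not pass (7 rose when adjusted over the list alone), with a median 0.12 above all genes (camera adjusted p = 0.147, and adjusted p = 0.482 with an estimated correlation, and fry adjusted p = 0.00327), and Pmaip1 rose from 0.629 ± 0.229 to 33.7 ± 11.3 FPKM. Of 14 prostate cancer driver genes, 5 rose, 0 fell and 9 did not pass (6 rose when adjusted over the list alone), with a median 0.11 above all genes (camera adjusted p = 0.278, and adjusted p = 0.397 with an estimated correlation, and fry adjusted p = 0.00284), and Trp53 rose from 10.3 ± 0.494 to 24.9 ± 4.52 FPKM. The driver list passed with no expression filter (camera adjusted p = 0.0384, over a range of 0.0384 to 0.572).

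**Figure D4:**
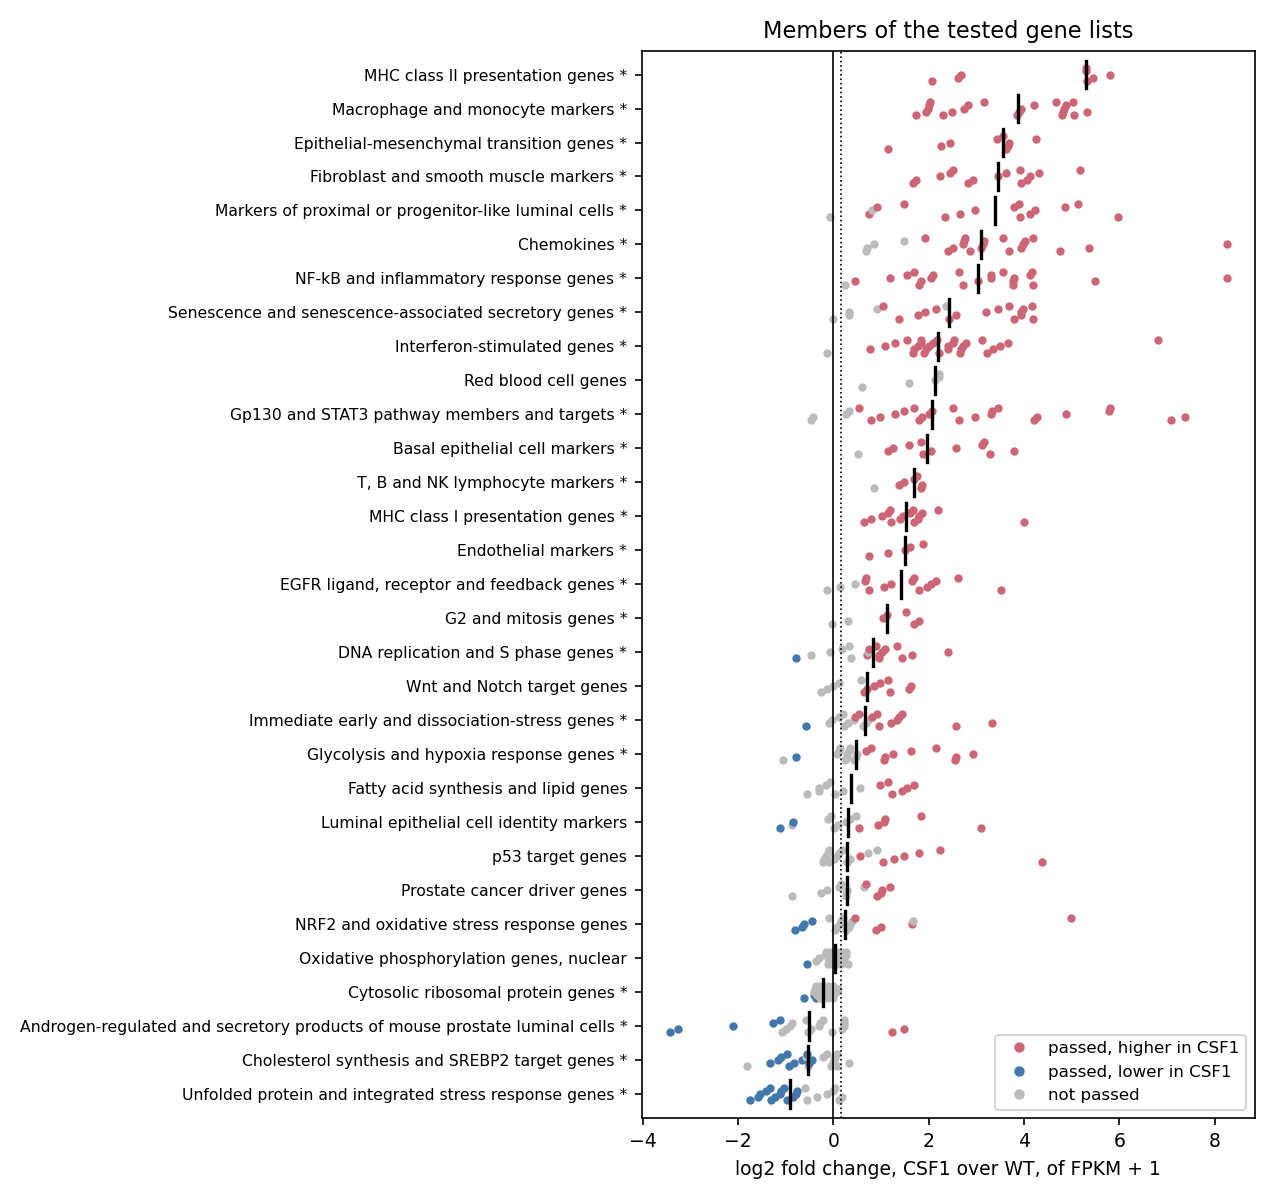
Log2 fold change of FPKM + 1 (CSF1 over WT) of each tested member of the 31 tested lists, coloured where the gene passed, with a black bar at each list's median, a dotted line at the median of all genes (0.17) and an asterisk at lists that passed. Of the 31 lists, 19 passed as higher and 4 as lower.

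The comparison cannot assign a transcript to luminal cells or to other cells in the same sort. For Spink1, Sbp and Sbpl, skipped by Cufflinks in some libraries, no comparison was made.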

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

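Of the tests in this part, that of loci skipped for too many fragments was chosen only after the result was seen. The tables list each transcript separately, which the comparisons by gene do not use. In the CSF1 libraries all of the Csf1 signal lay on the transcript NM_001113530 (2324 nt), at 1082, 1326 and 1678 FPKM in replicates 3, 5 and 8 (mean 1362, SD 299.97). This transcript was listed at 0 in every WT library, with Cufflinks' upper bounds of 0.0297, 0.0271 and 0.0348 FPKM in replicates 3, 5 and 8. In WT, the signal lay on NM_007778 (4176 nt), at 1.54, 0.549 and 2.67 FPKM, and on NM_001113529 (3291 nt), at 0, 1.70 and 1.31 FPKM. Both of these were listed at 0 in the CSF1 libraries. The transcripts differ at the 3' end: exon 9 of NM_001113530 lies at 107745595 to 107745840 on chromosome 3, while exon 9 of the other transcripts lies at 107741048 to 107743145. NM_001113530 and NM_007778 share an exon 6 of 1016 bp, which is 131 bp in NM_001113529. The sequence of the transgene is not given in the sources used here, and whether its 3' end matches that of NM_001113530 was not tested.

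Among 1738 genes with at least 2 transcripts and 5 FPKM in each library, 13 had 1 most abundant transcript in all WT libraries and another in all CSF1 libraries. They included Arrdc4, Lmo4, Tpm1, Tbx3 and Capn1, named after their values were seen. Another of the 10 splits of the libraries gave 9 such genes, and 10 splits are too few for a share under 0.05. No explanation was tested for these genes.

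Among the called genes, 14 with a mean of at least 5 FPKM in 1 group were listed at 0 in every library of the other group, 9 in WT and 5 in CSF1. Of the 12 that could be placed in the annotation, 7 (58.3%) had exons that overlap another listed gene's exons, against 520 of 2733 other called genes that also had a mean of at least 5 FPKM in at least 1 group and a place in the annotation (19.0%), a ratio of 3.07 (Fisher's exact test, two-sided, p = 0.00299), so reads assigned to 1 of the overlapping genes may account for part of these zeros. The partners were compared by their group means only, with no threshold applied. The partner's mean moved against the gene in 3 of the 7: Psme1 (with Emc9, 14 bp) from 65.6 to 202 FPKM, Lpp (with Lppos) from 2.94 to 6.11 FPKM and Yif1b (with 2200002D01Rik) from 77.9 to 52.7 FPKM. In 3 the partner's mean was higher in CSF1, like the gene's: Ctsa (with Pltp) from 23.8 to 53.04 FPKM, Tesk1 (with Cd72) from 7.25 to 12.5 FPKM and Krr1 (with Glipr1) from 5.32 to 6.58 FPKM. Thoc6, the partner of Hcfc1r1, was listed at 0 in both groups. A shift of reads to the partner is therefore not shown for those 4. For the first 3, opposite moves of the means alone do not show it either, since the partners can change on their own. The skipping of loci with too many fragments also produces zeros, by the definition of that status. All 6 wild-type values at 0 of Sbpl and Spink1, genes left out of the tests, carry it, so they test nothing further. The skipping leaves the 14 genes themselves unexplained, because genes with that status were left out. Cufflinks' upper bounds at the zeros of the 14 genes ran from 0 to 0.457 FPKM, and a bound of 0 is no interval. A real absence in 1 group stays open, as in Ifi27l2a, which overlaps no listed gene, and no test here separates it from a failed estimate.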

How the results depend on the processing

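The alternatives that keep failed-status genes, leave out overlapping exons or rescale FPKM outside the 5 most abundant genes were added after the data were examined. No named gene or list that passed reversed, while the balance of higher and lower genes turned round with quantile normalization. Csf1 kept its call in every alternative and leave-out (log2 change 7.48 to 10.39). Not every gene or list could be tested in every alternative: 246 of 376 named genes and 26 of 31 lists could, with 291 genes and 26 lists at a mean of at least 5 FPKM. Of the 246 genes, 193 kept their call in all alternatives and leave-outs, and of the 26 lists tested throughout 17 did in all but the estimated correlation. Against 3549 called genes with FPKM as deposited, 2731 higher and 818 lower, quantile normalization called 1694 higher and 2362 lower genes, with 2511 among the 3549, and median-ratio scaling called 1677 lower; both remove a shift common to all genes, which moves genes between directions by construction. The rescaling outside the 5 most abundant genes called 1239 lower, and 1379 lower with failed-status genes left out of it. A mean of at least 5 FPKM gave 1761 higher genes and 3 other cell type lists in place of 5, with fewer genes tested, and a 2-fold minimum gave 1900 genes, 1630 higher and 270 lower, by a stricter threshold. Leaving out libraries or pairs gave 1860 to 3156 called genes, 1519 to 2489 higher and 341 to 850 lower, with fewer samples. With an estimated correlation camera called 0 lists higher (main 19), 0 lower (main 4) and 0 other cell type lists; the cause was not tested. At an unadjusted p under 0.05 that test called 3 higher, 2 lower and 0 cell type lists, and fry, after adjustment, 25 higher and 3 lower. The replicate block gave 2883 higher and 890 lower genes, with 3428 among the 3549, ended the G2 and mitosis call (camera adjusted p = 0.0555, 0.00125 to 0.203 over the other alternatives) and, beyond 4 calls of named genes ended and 5 added, changed no other list call. The count-based alternative (DESeq2 size factors) was not run, since the tables hold FPKM. Fragment counts are not given, so no limit in counts was set for genes listed at 0.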

Other observations

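Of the tests in this part, those of the 5 most abundant genes, of a common loss of luminal share and of macrophages in the sorted cells were chosen only after the result was seen, as were the ratios of replicates 8 and 5 between progenitor and macrophage lists and the scan of gene families. The others were set before. The first pattern was the excess of higher over lower genes in CSF1 libraries (77.0% of called genes). Deeper CSF1 libraries as its whole cause are argued against, because among called genes with a mean of at least 50 FPKM 61.3% were higher (exact Clopper-Pearson 95% interval 57.4% to 65.0%), and this level leaves little to a gain in detection. The share was 88.3% from 1 to 5 FPKM and 75.8% from 5 to 50 FPKM, so a part played by depth in low genes stays open. The interval above treats genes as independent, does not measure the spread between libraries and was taken with FPKM as deposited only. The scaling of FPKM also stays open. Quantile normalization brought the share to 41.8%, under the 55% set beforehand for scaling as the cause. That rule was met, but this normalization centres all genes whatever the cause, a limit the rule did not hold. The value therefore decides nothing. With FPKM rescaled to the genes outside the 5 most abundant, the share of higher genes was 64.3%, but those 5 included genes skipped in WT. With the 5 taken from the genes with no failed status, which held a smaller share in each CSF1 library than in the WT library of the same number, it was 60.9%. Both values lie between the 55% set for a whole cause and the 70% set against it. Neither rescaling accounts for fragments at the loci skipped in WT, which are written as 0 or left out. The part of dominant genes in the excess is therefore not settled. The real split called 3549 genes and the highest of the other 9 splits 5, and 10 splits are too few for a share under 0.05. Other splits that part all same-numbered pairs called 0 genes. An effect of the Csf1 transgene on the direction of change stays open as untested.

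The second pattern was the rise of markers of other cell types. A lower luminal share alone would raise the markers of every other type alike. Between CSF1 replicates 8 and 5, however, the median log2 ratio was 1.54 for macrophage markers and -1.08 for stroma markers. This difference of 2.63 (permutation test over genes, two-sided, p = 1e-05, the smallest that 100000 resamples can give) argues against 1 common loss with the same mix of other cells in every CSF1 library. Between CSF1 replicates 8 and 3 that difference was 2.54 (permutation p = 1e-05). Both comparisons rest on replicate 8. In CSF1 replicates 3 and 5 the mean log2(FPKM + 1) was 4.04 and 4.34 for the macrophage list and 4.37 and 4.86 for the stroma list. The permutation p-values here treat genes as independent and set 1 library against 1 other, so they do not measure the spread between libraries. Macrophages in the sorted cells stay open as the source of the macrophage list. All 22 tested markers rose. Their log2 ratios of CSF1 replicate 8 to 3 had an SD of 0.676 around a median of 1.93. This met the rule written for macrophages as the source. It decides nothing, since the SD was lower for the luminal progenitor (0.304) and MHC class I (0.278) lists. The most abundant of the markers were Lyz2 at 703 FPKM, Ctss at 249 FPKM and Cd14 at 238 FPKM in CSF1. In WT, 10 of the 22 had a mean of at least 1 FPKM, and Ctss is also in the MHC class II list. Whether the sort excluded macrophages is not known, since its markers and gates are not given in the sources used here. Macrophages attached to luminal cells or carried over could not be checked. Macrophage RNA as the whole source of the luminal progenitor list is argued against, since that list's median ratio of replicate 8 to 3 lay at 0.44, a difference of -1.49 from the macrophage list (permutation p = 5e-05). For replicate 8 to 5 the medians were 0.67 and 1.54, a smaller difference of -0.87 (permutation p = 0.00015), so a part played by macrophage RNA stays open. Of the 16 progenitor genes, 15 had a WT mean of at least 1 FPKM and 0 were in another list. More progenitor-like luminal cells in the sort, and a change within luminal cells under the transgene, stay open as untested.

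Between the CSF1 libraries, replicate 8 stood above replicates 3 and 5 for immune lists and red blood cell genes. The median log2 ratio of replicate 8 to 3 and to 5 was largest for red blood cell genes, at 3.13 and 3.16. It was 1.73 and 1.52 for MHC class II, 1.70 and 1.66 for chemokines and 1.31 and 1.23 for lymphocyte markers. It was 0.30 and 0.75 for interferon-stimulated genes and 0.24 and 0.34 for MHC class I. For luminal identity it was -0.03 and 0.13. Stroma went the other way, at -0.61 and -1.08, as did androgen-regulated and secretory genes, at -0.56 and -0.66, and unfolded protein response genes, at -0.59 and -0.43. In WT, where the same numbers occur, replicate 8 was also the highest for some of these lists. The mean log2(FPKM + 1) in WT replicates 3, 5 and 8 was 0.90, 1.04 and 1.79 for macrophage markers, 2.29, 2.48 and 3.23 for chemokines and 1.52, 1.95 and 2.38 for MHC class II. It was 0.12, 0.22 and 0.21 for lymphocyte markers and 2.96, 2.07 and 3.01 for red blood cell genes. An effect shared by the libraries of 1 number stays open for the first 3.

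A scan of 324 families of genes that share the stem of their symbol found 18 that rose and 17 that fell by camera, none with an estimated correlation (adjusted p = 0.987 for those named here). The directions given were the same under quantile normalization and median-ratio scaling. Of 12 secretoglobin (Scgb) genes, 11 fell, with a median log2 change of -3.27 (camera adjusted p = 2.15e-11), and Scgb1a1 rose from 0.188 ± 0.325 to 18.9 ± 10.1 FPKM. Histone (Hist) genes fell in 15 of 61 and rose in 1, with a median of -0.27 (camera adjusted p = 1.48e-08). Keratins (Krt) rose in 13 of 16 genes with a median of 2.62 (camera adjusted p = 0.000341), with Krt6a going from 1.13 ± 0.872 to 71.0 ± 31.0 FPKM and Krt16 from 0.531 ± 0.0525 to 11.8 ± 7.70 FPKM. Galectins (Lgals) rose in 5 of 7 genes with a median of 3.26 (camera adjusted p = 0.0162), Lgals3 from 95.5 ± 20.1 to 949 ± 343 FPKM and Lgals1 from 3.86 ± 1.29 to 95.6 ± 27.1 FPKM. All 6 suppressors of cytokine signalling (Socs) rose, with a median of 1.34 (camera adjusted p = 0.0230). Genes of protein secretion (Sec) fell in 8 of 22 and rose in 1, with a median of -0.39 (camera adjusted p = 0.000341), and Sec11c went from 1435 ± 176 to 751 ± 84.5 FPKM.

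Among the genes left out of the tests, Spink1 was at 10849 FPKM in CSF1 replicate 3, 13903 in replicate 5 and 17357 in replicate 8, and was skipped in WT, where it is written as 0. Sbpl was at 2904, 6389 and 5917 FPKM in the CSF1 libraries and was skipped in WT. A skipped locus gives no level, so no change was estimated for these genes. The skip marks too many fragments at the locus, and the WT libraries were the shallower ones. The 0 written in WT therefore does not mean a low level. If the limit was the same in all libraries, these loci held more fragments in WT than in CSF1. The limit and the fragment counts are not given, so the direction was not tested.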
